A study of Mus musculus with 2 samples.

How the data were processed

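Fluorescent cells of α-gustducin-GFP mice were freed from the epithelium around the papillae with dispase, elastase and TrypLE and sorted by size, singlet gates, exclusion of the dead-cell dye 7-AAD and GFP, per the labels' protocols. Cells were captured on the BD Rhapsody bead system, and cDNA was amplified by TAS-Seq and sequenced on a NovaSeq instrument, per the series design. Hashtag libraries were also prepared, per the labels' protocols, and were not analysed here. There were 2 samples, 1 library from fungiform papillae (FP) and 1 from the circumvallate papilla (CV), grouped by their tissue label.

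The deposited tables hold whole-number counts per gene and barcode, not normalized, per the values themselves. Per the submitters' processing notes the tools were cutadapt 2.10, Bowtie2 2.3.4.1 and Seurat 2.3.4, with build mm10, and per the series design reads were aligned to mouse reference RNA, barcodes were chosen with DropletUtils and counts were adjusted by distribution-based error correction. Whether molecular barcodes were collapsed was not given in the sources used here. Barcodes summed to as many as 4088415 counts, and genes with high counts in some cells had single counts in others, so the counts were treated as possibly holding PCR copies. Poisson and binomial intervals and floors then cover counting error only and are too narrow where copies were counted.

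The authors state filters on genes, mitochondrial and ribosomal RNA percentages and Gnat3, in a form that can be read in several ways. The tables hold 90 barcodes, the stated cell number, of which 85 had more than 500 genes. The main set kept barcodes with more than 500 genes and with Gnat3 above 0.9 on ln(1 + counts per 10000), the scale of Seurat, which left 53 cells. The base of the logarithm was read as the natural one. The mitochondrial limit read as more than 0.6% removed no cell, and read as at most 0.6% it left 0 cells. Read as fractions, at most 60% mitochondrial and 10% ribosomal RNA counts, the limits left 20 FP and 29 CV cells. No mitochondrial or ribosomal RNA limit was applied to the main set. Doublets were not called in so few cells. A gene missing from one table (18985 genes were listed for FP, 20362 for CV and 21888 in either) was taken as 0 there, although each table also lists genes at 0 (1043 in FP and 895 in CV).

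Kept cells were pooled per library and expressed as CPM. Sums carry exact Poisson 95% intervals, ratios the exact conditional binomial interval, and shares of cells the exact Clopper-Pearson interval. A share of 0 also carries a floor of 3 cells of the total. A fold against 0 counts is worded as at least a value, by a floor of 3 counts over the pooled group. It is not a confidence bound, since the exact 95% lower limit is smaller (1308 against 1609 for Tas2r107). Ratios are on the log2(CPM + 10) scale, which understates the change of low genes. The gene rule, lists, markers and all alternatives but those named as later choices were fixed before the data were examined. Among genes with a symbol (not gene models, mitochondrial or ribosomal RNA genes), at least 100 CPM and detection in at least 25% of the cells of the higher library (2452 genes), the 12 largest log2 ratios in each direction were named, each still 2-fold with the highest cell left out. For the 2 receptor classes the rule took 8 genes in each direction without the taste receptors. In 17 gene lists and 12 marker lists, members with at least 10 CPM in either library were eligible, members with at least 50 CPM could be named, preferring the 4 largest, and Gnat3, the Tas1r genes, Gna14 and the Tas2r genes could always be. Members below that level (Abcc8, Calhm1, Ddx3y, Eif2s3y, Hspa1b, Krt13, Krt6a, Otop1, Pecam1, Scg3 and Uty) were named after their values were seen. Some genes that met these rules are not reported here, and counts and medians include them. The median log2 ratio of a list was placed among 10000 random lists matched on mean CPM in 20 bins, as a description of these 2 libraries.

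A cell was called on for a gene at 50 CPM or more, a level chosen after the data were seen, because genes with high counts in some cells had 1 to 10 counts in most others. In shallow barcodes that level takes few counts. In 1 kept CV barcode of 42809 counts, 3 Tas1r2 counts made 70.1 CPM. The shallowest kept FP cell had 193718 counts, so the rule is looser in the shallow CV cells. Shares at 1 count or more are the planned values. Total counts were equalised by thinning each cell to 71770 counts, the 10th percentile of kept totals. Counts outside mitochondrial and ribosomal RNA still differ between the thinned cells. Barcodes with more than 500 genes were clustered on ln(1 + counts per 10000) with 1000 variable genes, 15 principal components, 10 neighbours and Leiden resolution 0.8 (scanpy 1.11.5, leidenalg 0.10.2). Gene positions were taken by symbol from GENCODE release M21 on mm10, where Vprbp had no entry. Alternatives were other readings of the cell filter, other detection rules, mean CPM per cell, a pseudocount of 1, no low-value filter, totals without mitochondrial and ribosomal genes, TMM scaling (edgeR 4.0.16, R 4.3.3) and leaving out the highest cells. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The planned comparison of receptor classes in CV had no cells on one side and was made in FP instead, at 50 CPM, since FP also had 0 such cells at 1 count.

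The gene comparison was tested on simulated data, with counts drawn from the pooled profile at the real cell totals and 200 genes changed in FP against CV. Over 1837 genes, 100% of the 100 genes changed 2-fold and 100% of the 100 genes changed 8-fold came out within 0.3 of the log2 ratio that the pseudocount allows, and the naming rule chose 24 of 24 genes from the 8-fold set. A simulated list of 10 genes raised 2-fold lay above 100% of the random lists, and a list of 10 unchanged genes lay above 79.3% of them. All simulated cells shared the pooled profile, so genes on in some cells and off in others were not simulated, nor were PCR copies. The simulation therefore checks the calculation only. It cannot show how far such differences between cells, or copies, move the ratios of the real data.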

Results

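Single taste cells were profiled from mice in which cells making α-gustducin, the taste G protein subunit encoded by Gnat3, carry green fluorescent protein. Fluorescent cells were sorted from the fungiform papillae (FP) of the front of the tongue and from the circumvallate papilla (CV) at its back, with 1 library for each. There were 29 cell barcodes for FP and 61 for CV, which together are the 90 cells that the series states. After a limit of more than 500 genes and of Gnat3 above 0.9 on the natural log scale, 21 FP cells and 32 CV cells were kept. The kept FP cells summed to 22646953 counts, with 193718 to 3190340 counts and a median of 6480 genes per cell. The kept CV cells summed to 29535917 counts, with 32726 to 3447628 counts and a median of 5524 genes per cell. With 1 library per group no replicate check was possible, and no test of the difference between the 2 libraries was made. Every interval below is a 95% interval that covers counting error only. How the 2 libraries relate to animals was not given in the sources used here.

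**Figure D1:**
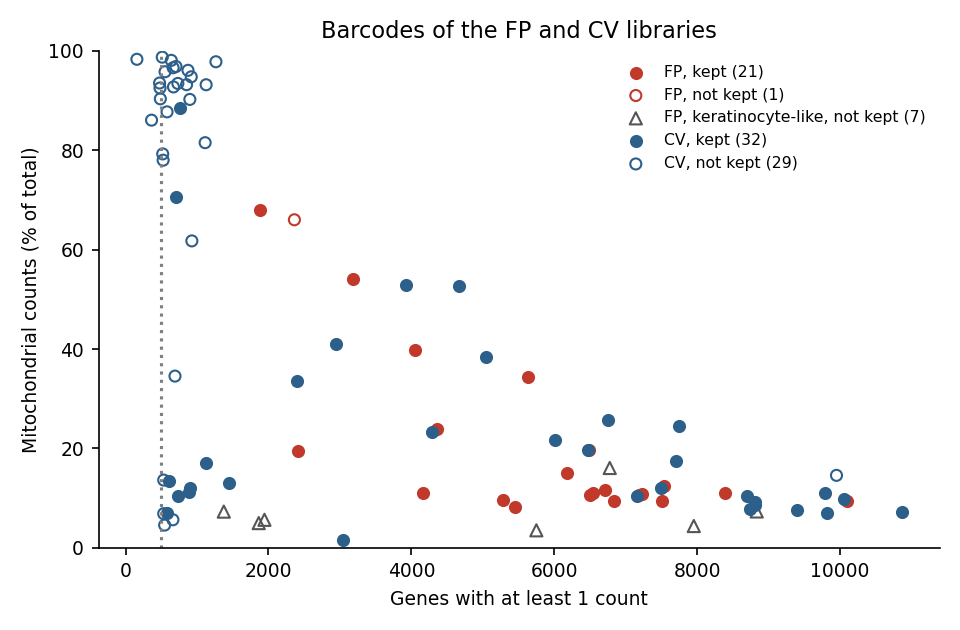
Each point is 1 barcode, placed by genes with at least 1 count (x) and by the mitochondrial percentage of its counts (y), with the 500-gene limit dotted. Filled points are the 21 FP and 32 CV kept cells, open circles and triangles are barcodes not kept, and most CV barcodes that were not kept have under 1000 genes and over 80% mitochondrial counts.

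The sorted barcodes fell into 4 clusters, of which 2 carried type II taste cell markers and 1 was keratinocyte-like. Cluster 1 (11 FP and 12 CV barcodes) had raised Gnat3, Trpm5, Itpr3, Gng13 and Pou2f3. Cluster 3 (8 FP and 20 CV barcodes) had raised Gnat3, Gng13 and Pou2f3. Both were therefore type II-like, the class of taste cell that detects sweet, umami and bitter compounds. Cluster 4 held 7 FP barcodes and no CV barcode, and it was led by the keratin genes Krt13, Krt76, Krt16 and Krt6a and by Krtdap and Lor, with 12 of 17 lingual keratinocyte markers raised. Its median Gnat3 level was 9.92 CPM (counts of a gene scaled to a common total) against 5320 CPM in the kept FP cells, and none of its barcodes was kept. Cluster 2 (3 FP and 24 CV barcodes) was led by Gabra2, Gcm1 and Rhox8, followed by mitochondrial genes. Its median mitochondrial share was 88.6%, and it stayed unnamed. Of its barcodes 8 were kept, 2 in FP and 6 in CV. Cluster 4 came from 1 library, so it may be a property of that library. The median mitochondrial share of kept cells was 11.1% in FP and 12.5% in CV, but it reached 68.03% in 1 kept FP barcode and 70.6% and 88.6% in 2 kept CV barcodes, and another kept CV barcode had 79.0% ribosomal RNA counts.

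Most cells of both papillae had at least 1 of the 34 bitter receptor (Tas2r) genes, and part of them had Tas1r3, the shared subunit of the sweet and umami receptors. At 1 count or more, the rule fixed before the data were examined, 20 of 21 FP cells (95.2%, Clopper-Pearson interval 76.2 to 99.9) and 29 of 32 CV cells (90.6%, 75.0 to 98.0) had a Tas2r. Tas1r3 was seen in 16 of 21 FP cells (76.2%, 52.8 to 91.8) and in 17 of 32 CV cells (53.1%, 34.7 to 70.9). Tas1r1, the umami receptor subunit, was seen in 19 of 21 FP cells (90.5%) and 16 of 32 CV cells (50%), and Tas1r2, the sweet receptor subunit, in 4 of 21 (19.05%) and 21 of 32 (65.6%). These shares include stray counts, because 6 of the 7 keratinocyte-like barcodes also had a Tas2r count and 3 of 7 a Tas1r3 count, at median depths of 1679950 counts against 1141640 in kept FP cells and 543963 in kept CV cells. At 50 CPM or more, a rule chosen after the stray counts were seen, 0 of 7 keratinocyte-like barcodes had either receptor, which allows a share of up to 42.9% by a floor of 3 barcodes (Clopper-Pearson upper limit 40.96%). By that rule a Tas2r was on in 13 of 21 FP cells (61.9%, 38.4 to 81.9) and in 28 of 32 CV cells (87.5%, 71.0 to 96.5). Tas1r3 was on in 8 of 21 FP cells (38.1%, 18.1 to 61.6) and in 7 of 32 CV cells (21.9%, 9.28 to 39.97). Tas1r1 was on in 3 of 21 FP cells (14.3%, 3.05 to 36.3) and 8 of 32 CV cells (25%, 11.5 to 43.4), so its order turned around, and Tas1r2 in 2 of 21 (9.52%, 1.17 to 30.4) and 4 of 32 (12.5%, 3.51 to 28.99). Among the 4 CV cells with Tas1r2 on, 1 was on by 3 counts in a barcode of 42809 counts. With 1 library per papilla these differences were not tested.

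Both receptor families were found in the same cells. At 1 count or more, 16 of 20 FP Tas2r cells (80%, 56.3 to 94.3) and 17 of 29 CV Tas2r cells (58.6%, 38.9 to 76.5) had Tas1r3, against 76.2% and 53.1% if the detections were independent. At 50 CPM these were 4 of 13 FP cells (30.8%, 9.09 to 61.4) and 7 of 28 CV cells (25%, 10.7 to 44.9), against 38.1% and 21.9%. Each of the 7 CV cells with Tas1r3 also had a Tas2r, while 4 of the 8 FP cells with Tas1r3 had none at 50 CPM. Tas1r3 ranged from 52.8 to 760 CPM in the CV cells with both and from 109 to 483 CPM in the FP cells with both, and it was at most 0.981 CPM in the keratinocyte-like barcodes. The highest CV value came from a shallow barcode (98657 counts) in a run of adjoining barcode numbers treated below. The lowest came from 14 Tas1r3 counts in a barcode with 52.9% mitochondrial counts. Thinned to 71770 counts per cell, which left out 6 CV cells, the shares of Tas2r cells with Tas1r3 were 46.7% in FP and 41.7% in CV at 1 count or more.

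**Figure D2:**
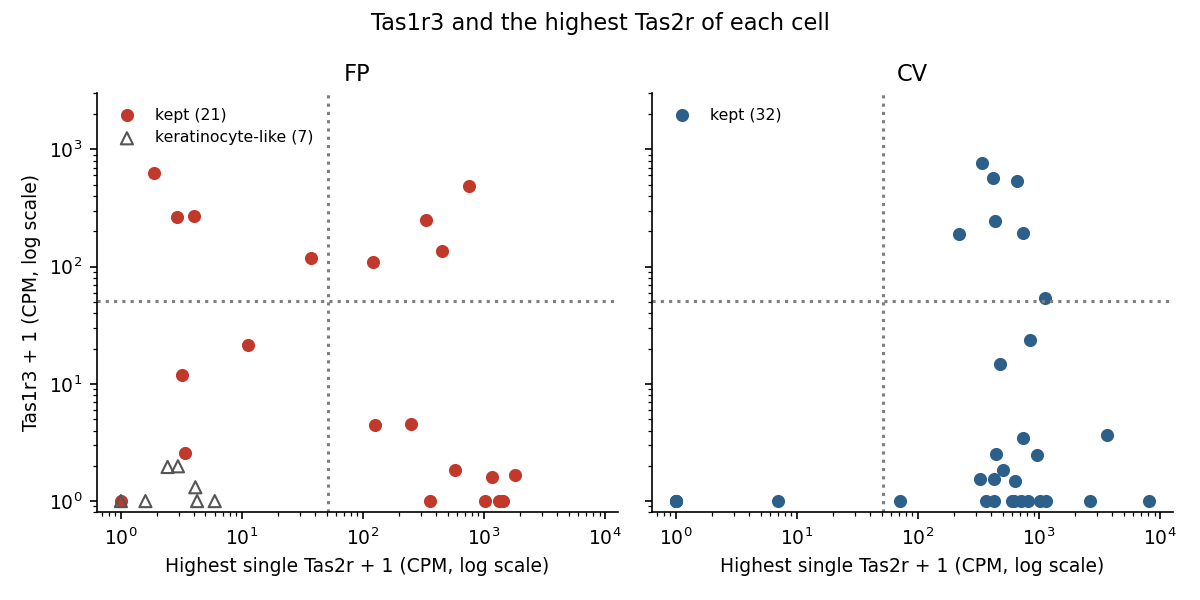
Each point is 1 cell, with its highest single Tas2r level on the x axis and its Tas1r3 level on the y axis, both in CPM plus 1 on log scales, for FP (left) and CV (right). Dotted lines mark 50 CPM, triangles are the 7 keratinocyte-like barcodes, and the upper left region holds 4 FP cells and 0 CV cells.

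CV cells carried a wider set of bitter receptors than FP cells. Of 27 Tas2r genes with at least 10 CPM in either library, 21 were at least 2-fold higher in CV and none was at least 2-fold higher in FP, with summed levels of 837 CPM in FP and 2042 CPM in CV. The median log2 ratio of FP over CV was -1.36, or -2.58 with the 6 members at 0 in FP set to the floor of 3 pooled counts and no pseudocount, and 0 of 10000 random lists matched on expression had a lower median. The median kept its sign under each of 13 alternatives. Tas2r107, on chromosome 6 from 131659118 to 131660149 (mm10), had 0 counts in FP and 213 CPM (208 to 218) in CV and was on in 17 of 32 CV cells. That is at least 1609-fold higher by the floor of 3 counts, with an exact lower limit of 1308. Tas2r106 reached 97.4 CPM in FP and 261 CPM in CV and was on in 5 and 20 cells. Tas2r118 reached 52.4 and 175 CPM, and Tas2r117 reached 72.6 and 204 CPM. Tas2r105 went the other way, with 355 CPM (347 to 362) in FP against 270 CPM (264 to 276) in CV, a ratio of 1.31. Tas2r120, Tas2r131, Tas2r135, Tas2r143 and Tas2r144 had 16.8 to 48.6 CPM in CV. Unlike Tas2r107, they were not listed in the FP table and were taken as 0 there. At 50 CPM, a Tas2r cell held a median of 2 receptors in FP (1 to 13) and 6.5 in CV (1 to 16), and 14 different receptors were on in 21 FP cells against 29 in 32 CV cells. At 1 count or more these were 23 and 33, and at 3 counts or more 20 and 32. Over draws of 21 CV cells, a comparison chosen after the data were seen, 27.4 receptors were expected at 50 CPM, 30.7 at 3 counts and 32.03 at 1 count. Thinned to the same total counts and counted at 3 counts or more, the medians were 3 and 8 receptors. Many of these genes are close paralogs on chromosome 6, and how reads matching several of them were assigned was not given in the sources used here, so levels of single receptors are uncertain.

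**Figure D3:**
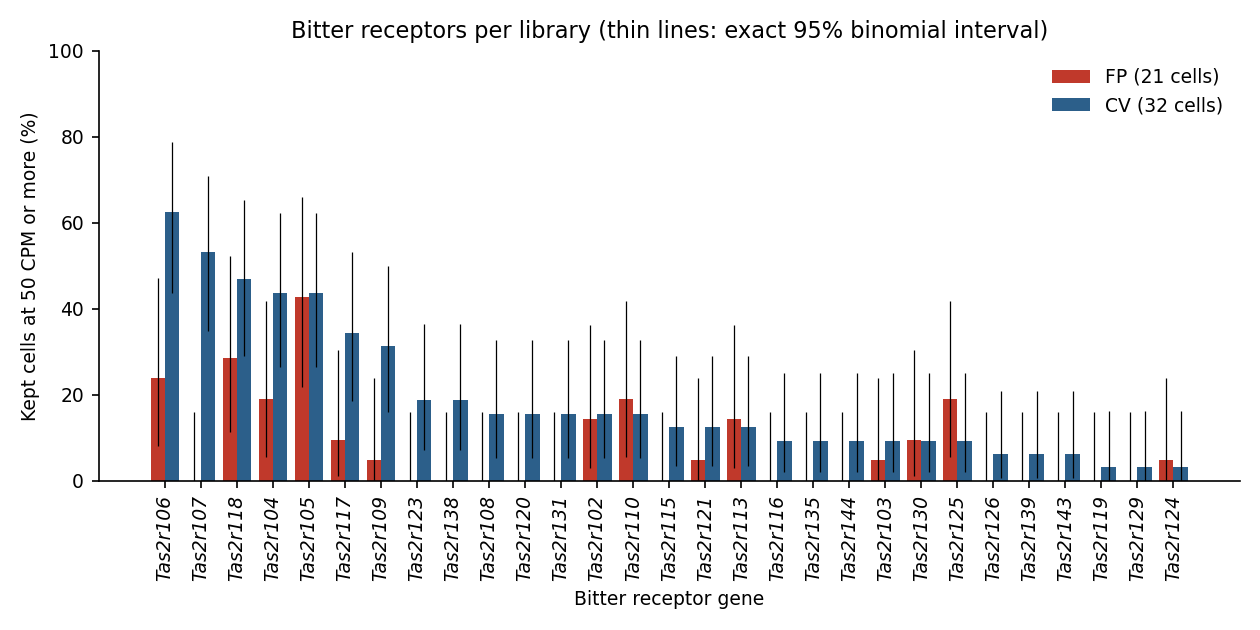
Bars give the percentage of kept cells at 50 CPM or more for each of 29 bitter receptor genes (x axis), in FP (21 cells) and CV (32 cells), with exact 95% binomial intervals as thin lines. The CV bar is higher for 24 genes and the FP bar for 5, with Tas2r107 on in 53.1% of CV cells and 0 FP cells.

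In the kept cells, most core genes of the taste transduction pathway were at like levels in the 2 papillae. Cells of both were sorted and kept by Gnat3, a member of that pathway. The likeness may follow from this selection and was not tested apart from it. Of 11 measured members of the type II transduction list, 10 lay within 2-fold, with a median log2 ratio of 0.13 that changed sign under 4 of 13 alternatives. Gnat3, by which cells were sorted and kept, had 5223 CPM (5194 to 5253) in FP and 4372 CPM (4348 to 4396) in CV. The β and γ partners Gnb3 (6518 and 5164 CPM) and Gng13 (3334 and 3561 CPM), the phospholipase Plcb2 (2930 and 2129 CPM) and the cation channel Trpm5 (1952 and 1783 CPM) were at like levels. Calhm1, a subunit of the ATP release channel, was the exception at 0.309 and 12.02 CPM, on in 0 and 1 cells. Of the sweet and umami receptors (median log2 ratio 0.47, with 8103 of 10000 random lists lower and the sign changing under 3 of 13 alternatives), Tas1r1 had 614 CPM (604 to 624) in FP and 73.9 CPM (70.8 to 77.0) in CV. That FP level came mainly from 2 cells with 5415 and 5800 CPM, and Tas1r1 was on in 3 of 21 FP cells and 8 of 32 CV cells. Tas1r2 had 26.8 and 16.5 CPM, and Tas1r3 had 132 and 99.2 CPM. These CV levels depend on the Gnat3 limit. It left out 1 CV barcode with 9041 Tas1r2 and 2582 Tas1r3 counts, against 486 and 2930 in the kept CV cells together. With no Gnat3 limit the median of this list was -0.73, on the CV side. Gna14, a Gq-family subunit, was not listed in FP and was taken as 0 there. It had 13.6 CPM (12.3 to 15.0) in CV and was on in 3 cells. That is at least 103-fold higher by the floor of 3 counts, with an exact lower limit of 83.2.

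Among the genes furthest apart between the papillae, Tlx1, Kit, Kcnj11, Tmem45b, Arc, Fgf14 and Cd44 were higher in FP. Tlx1, a homeobox transcription factor gene on chromosome 19 from 45150680 to 45156943, had 130 CPM (126 to 135) in FP and was on in 7 of 21 cells. It was not listed in the CV table and taken as 0 there. By the floor of 3 counts it was at least 1282-fold higher in FP, with an exact lower limit of 1042. Kit, a receptor tyrosine kinase, had 159 CPM (154 to 165) in FP and 0.440 CPM (0.234 to 0.753) in CV and was on in 7 and 0 cells. Kcnj11, the pore of the ATP-sensitive potassium channel, had 139 and 0.779 CPM and was on in 7 and 0 cells. Tmem45b (376 and 4.13 CPM), the activity-regulated gene Arc (259 and 4.13 CPM), the sodium channel partner Fgf14 (379 and 13.1 CPM) and the hyaluronan receptor Cd44 (591 and 45.7 CPM) were each on in at least 10 FP cells. Pacsin1, Ephb3, Cd59a and Immt, at 127, 111, 105 and 165 CPM in FP, were also among the 12. Keratinocyte RNA was present at a low level in the same cells, with Krt13 at 32.8 CPM in kept FP cells against 0.0677 CPM in kept CV cells.

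Among the genes furthest apart in the other direction, Mgll, which encodes monoacylglycerol lipase, had 1325 CPM (1312 to 1338) in CV and 27.99 CPM (25.9 to 30.3) in FP, a ratio of 47.3 (43.8 to 51.3), and was on in 13 and 4 cells. Edil3, a secreted matrix protein gene, had 521 CPM in CV and 1.02 CPM in FP and was on in 13 and 0 cells. The calmodulin-binding protein gene Nrgn had 246 CPM in CV and was not listed in FP. By the floor of 3 counts it was at least 1856-fold higher in CV, with an exact lower limit of 1509. Nefl, the light neurofilament gene, had 229 CPM in CV and 0.132 CPM in FP, and Pik3r5, a phosphoinositide 3-kinase regulatory subunit gene, had 239 and 2.43 CPM. Fyb (584 CPM in CV), Ascc3 (546 CPM), Cbr2 (415 CPM), Vprbp (370 CPM), Serpinb9e (291 CPM) and Col4a4 (191 CPM) each had under 1.4 CPM in FP and were on in 6 to 11 CV cells. Serpinb9e belongs to a family of near copies, so its level is uncertain. Across 10918 genes with at least 10 CPM in either library, the median log2 ratio was -0.05 and the Pearson correlation of the log2 levels was 0.68, a figure across genes, which are not independent replicates. With the Gnat3 limit dropped, the log2 ratio of FP over CV fell from 4.02 to 0.41 for Kit, from 4.77 to 1.71 for Tmem45b, from 3.43 to 2.25 for Cd44 and from 3.34 to 2.21 for Immt. One CV barcode that then entered had Kit at 683 CPM and Tmem45b at 587 CPM.

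**Figure D4:**
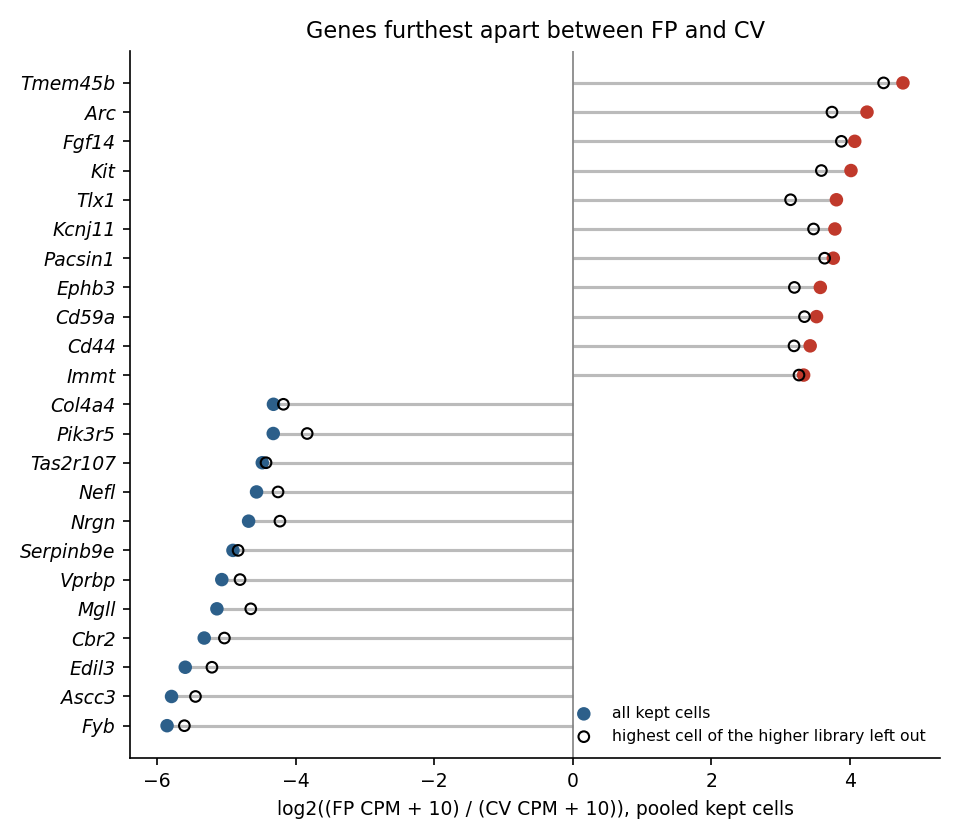
Filled points give log2((FP CPM + 10) / (CV CPM + 10)) over pooled kept cells for genes furthest apart, 11 with the higher level in FP and 12 in CV, red where FP is higher and blue where CV is higher. Open points give the same ratio with the highest cell of the higher library left out, a condition of the choice of genes.

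Genes shared with tuft cells, the chemosensory cells of other epithelia, leaned to CV. Of 20 measured tuft cell genes, 8 were at least 2-fold higher in CV and 2 in FP. The median log2 ratio was -0.90, or -0.95 with members at 0 set to the floor and no pseudocount, with 2 of 10000 random lists lower, and it stayed between -1.22 and -0.56 over 13 alternatives. Chat, the acetylcholine synthesis enzyme, had 0 counts in FP and 165 CPM in CV, at least 1244-fold higher and on in 10 of 32 cells. Rgs13, a regulator of G protein signalling, had 22.2 CPM in FP and 538 CPM in CV and was on in 2 and 9 cells. Sh2d7 (0.0883 and 82.0 CPM) and the leukotriene enzyme gene Alox5 (0.0442 and 53.8 CPM) were also higher in CV, while the cyclooxygenase gene Ptgs1 was higher in FP (223 and 57.02 CPM). The regulators of these cells were closer, with 8 of 11 within 2-fold, a median of -0.25 that changed sign under 1 of 13 alternatives, and 1390 random lists lower. Among them Pou2f3 had 404 and 350 CPM, Spib had 33.7 and 102 CPM, and Etv1 had 59.6 and 5.62 CPM, a ratio that turned to -1.24 on the log2 scale when the Gnat3 limit was dropped.

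Genes of the immediate early and dissociation list went both ways, with a median on the FP side under each of 13 alternatives. Of 18 measured members, 5 were at least 2-fold higher in FP and 4 in CV, with a median log2 ratio of 0.40 and 9628 of 10000 random lists lower. The median was 0.91 without the highest cell of each library and 1.15 without the 10% of cells with the highest totals. Egr1 had 1729 CPM in FP and 545 CPM in CV, Ier2 had 1276 and 411 CPM, Btg2 had 1176 and 354 CPM and Nr4a1 had 309 and 86.3 CPM. Hspa1a had 16.6 CPM in FP and 134 CPM in CV, and its near copy Hspa1b had 0.662 and 30.6 CPM, while Hspa8 (906 and 884 CPM), Hsp90aa1 (447 and 740 CPM) and Dnajb1 (61.3 and 26.6 CPM) were within 2-fold on the log2(CPM + 10) scale. Atf3 had 14.5 and 103 CPM, with 2 cells on in each library.

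Ion channel genes differed in both directions. Of 11 measured members of the channel list, 3 were at least 2-fold higher in FP and 3 in CV (median -0.51, or -0.12 with mean CPM per cell, 655 random lists lower). Beside Kcnj11, the pacemaker channel gene Hcn4 (57.6 and 18.7 CPM) was higher in FP, whereas the sodium channel gene Scn2a (9.05 and 70.8 CPM) and the potassium channel genes Kcnb2 (6.05 and 61.1 CPM) and Kcnj2 (53.9 and 130 CPM) were higher in CV. Of 4 sugar-sensing genes, Kcnj11 and its partner subunit Abcc8 (25.7 and 0.102 CPM) were higher in FP, and the glucose transporter gene Slc2a1 was at 186 and 157 CPM (median 1.03, 9692 random lists lower). That median ran from 0.73 to 2.48 over 13 alternatives, the highest with a pseudocount of 1, and was 3.94 with no pseudocount. The fat-sensing list had a median of 1.09 (0.90 to 2.92 over 12 alternatives, 1.64 with no pseudocount) with 9399 random lists lower, and Cd36 (362 and 28.6 CPM) was on in only 2 cells of each library and turned to -0.14 on the log2 scale without the 10% of cells with the highest totals.

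Adhesion and guidance genes moved both ways, with 4 of 16 at least 2-fold higher in each papilla. Their median of -0.34, or -0.37 with members at 0 set to the floor and no pseudocount, had 1364 random lists lower and changed sign under 2 of 13 alternatives. The semaphorin gene Sema7a (245 and 42.9 CPM) and the cadherin gene Cdh1 (421 and 166 CPM) were higher in FP, and Slit2 (15.3 and 115 CPM) and Sema3a (39.2 and 133 CPM) were higher in CV. Bdnf was at 367 and 449 CPM. Of the antigen presentation genes, B2m (76.4 and 4.50 CPM) was higher in FP and H2-Q4 (240 and 812 CPM) was higher in CV, with a list median of 0.02 (0.03 with members at 0 set to the floor and no pseudocount), 4996 random lists lower and a change of sign under 5 of 13 alternatives. H2-Q4 has close paralogs, so its level is uncertain. The interferon (median 0.00, 6004 random lists lower), G alpha (0.03, 6035), hormone receptor (-0.20, 3943) and cell cycle lists (0.12, 6171) had medians near 0, each changing sign under at least 3 of 13 alternatives. With members at 0 set to the floor and no pseudocount, the G alpha median was 0.06 and the interferon median 0.01. The sex-linked list (0.52, 8527; 0.26 to 1.39 over 12 alternatives and 1.71 with no pseudocount) held Xist at 879 and 1243 CPM and the Y-linked genes Ddx3y (19.2 and 0.0339 CPM), Eif2s3y (23.7 and 1.56 CPM) and Uty (0.839 and 18.1 CPM). A Y-linked gene was on in 2 FP cells with Xist at 1.52 and 8.29 CPM and in 2 CV cells with Xist at 817 and 6.51 CPM. Of the hormone and peptide list only Scg5 (55.2 and 54.6 CPM) and Scg3 (0.927 and 11.1 CPM) reached 10 CPM.

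Markers of other cell types were mostly low in the kept cells. Type III taste cell markers had 3 eligible members and a median of -1.77 (70 random lists lower), or -7.51 with members at 0 set to the floor and no pseudocount. Among them Syt1 had 0 counts in FP and 56.1 CPM in CV, on in 4 cells, and Otop1 had 0 counts and 24.1 CPM, on in 2 cells. Lingual keratinocyte markers leaned to FP (median 1.33, or 3.74 with members at 0 set to the floor and no pseudocount, 9994 random lists lower), and the median was 6.07 with the Gnat3 limit dropped. The 8 eligible keratinocyte markers summed to 518 CPM in FP and 326 CPM in CV. Of these markers 5 were at least 2-fold higher in FP and 0 in CV, with log2 ratios down to -0.38. Krt6a, a small part of those sums, had 48.3 CPM in FP and 0.102 CPM in CV, against a median of 18831 CPM in the keratinocyte-like barcodes. Type I markers (median -0.62, 2009 lists lower, -1.11 with no pseudocount) and precursor markers (-0.41, 3491, changing sign under 3 of 13 alternatives) included Scnn1a at 83.4 and 79.4 CPM and Sox2 at 118 and 65.3 CPM. The taste bud keratins Krt8 (4195 and 2104 CPM), Krt18 (2361 and 1407 CPM) and Krt19 (3741 and 2018 CPM) were under 2-fold apart, with a list median of 0.40 (8817 lists lower) that changed sign under 3 of 13 alternatives, and the type II marker median of 0.13 (6260 lists lower) changed sign under 5. Of the stromal list, Pdgfra (6.89 and 62.7 CPM) and Pecam1 (0 counts and 36.3 CPM) were eligible, with a median of -2.16, or -5.64 with Pecam1 at its floor and no pseudocount. No member of the salivary gland, immune, muscle, glia and melanocyte, or red blood cell lists reached 10 CPM.

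Cells with Tas1r3 alone could be set against cells with a Tas2r alone only in FP, and only at 3 counts or 50 CPM. At 1 count or more, the rule fixed in advance, 0 of 21 FP cells had Tas1r3 without a Tas2r (up to 14.3% by a floor of 3 cells, with a Clopper-Pearson upper limit of 16.1%), and no kept CV cell did by any of the 3 rules (0 of 32, which allows up to 9.38% by a floor of 3 cells, with a Clopper-Pearson upper limit of 10.9%). In FP, at 50 CPM and therefore by a rule chosen after the data were seen, 4 cells had Tas1r3 alone and 9 had a Tas2r alone. One of the 4 had 81.1 CPM of summed Tas2r over 5 receptors, none of them at 50 CPM. Plac8 had 693 CPM (676 to 711) in the Tas2r cells and 1.47 CPM (0.541 to 3.21) in the Tas1r3 cells and was on in 7 of 9 and 0 of 4. The carbonic anhydrase gene Car7 (412 and 0.983 CPM) and the ubiquitin ligase gene Rnf128 (544 and 9.34 CPM) were on in 7 of 9 Tas2r cells, with 0 and 1 of the 4 Tas1r3 cells on. Fezf1, a zinc finger gene, had 412 and 1.72 CPM and was on in 4 of 9 Tas2r cells. Tbcd (333 CPM) and Rps4l (273 CPM) were each on in 4 Tas2r cells, and Cd36 (936 CPM) and Col27a1 (298 CPM) in 2. The Col27a1 level came mainly from 1 cell, without which its log2 ratio of Tas1r3 over Tas2r cells moved from -4.78 to -1.20. On the Tas1r3 side, the ETS-family gene Etv1 had 321 CPM (304 to 339) against 0.344 CPM (0.0709 to 1.004) and was on in 3 of 4 cells. Fibp (371 CPM) and Dnajb2 (391.7 CPM) were on in 3 of 4 cells, and Supt3 (451 CPM), Spon2 (342 CPM), Tspan6 (328 CPM), Atp6v0e (329 CPM) and Dhx38 (310 CPM) in 2. Pooled Gnat3 was 3073 CPM in the Tas1r3 cells and 5989 CPM in the Tas2r cells, Gnb3 was at 3421 and 7223 CPM, and Plcb2 was at 2856 and 2993 CPM. The 4 Tas1r3 cells were unlike one another, with Gnat3 at 2140 and 660 CPM in the cells with Tas1r1 at 5800 and 5415 CPM, and at 5940 and 4820 CPM in the cells with Tas1r1 at 65.7 and 3.45 CPM.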

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

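The tests of shallow CV barcodes, of free RNA and of stray reads between adjoining barcodes were chosen after the result was seen, and the others were written down before.

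Barcodes outside the comparisons also held taste receptor signal. Of 29 CV barcodes that were not kept, 9 had a Tas2r at 50 CPM and at least 3 counts. So did 1 of the 1 FP barcodes outside both the kept cells and the keratinocyte-like cluster, which had 7720 CPM of summed Tas2r and 67.4 CPM of Gnat3. The 9 CV barcodes had mitochondrial shares of 4.58% to 93.5%. All but 1 of them, described next, were shallow, with 45614 to 168001 counts, where few counts reach 50 CPM. One CV barcode with 4088415 counts, left out because its Gnat3 was 14.9 CPM, had Gna14 at 1758 CPM, above the 0.734 CPM that 3 counts would give there. Its Tas1r2 was 2211 CPM and its Tas1r3 632 CPM, whereas the highest Gna14 among kept CV cells was 299 CPM.

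The 12 genes that led FP over CV were weighed against 2 technical explanations. RNA from the keratinocyte-like barcodes was measured by Krt13, which had 32.8 CPM in kept FP cells and 18854 CPM in those barcodes, a spill of 0.174%. The expected spill was a median of 4.1e-05 of the observed FP level over the 12 genes and at most 0.00214, for Tlx1, which argues against this source. The 8 kept CV barcodes that were shallow, mostly mitochondrial or rich in ribosomal RNA held 2.03% of the pooled CV counts. A 2-fold drop of a pooled level would need 50%, so the pooled levels do not rest on them. Shallow barcodes hold few counts by how they were chosen, so this is no independent test. Numbers of cells on, where each barcode counts alike, are not addressed by it. Papilla type, the animals used and the preparation of 1 library each stay open and were not tested.

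Among the CV barcodes, 6 had numbers within a span of 11, where numbers ran up to 863254, and 5 of them were kept. One of them had 1350869 counts and the other 5 had 45673 to 121188. If these were 1 cell or bead read under several barcodes, the shallow ones should correlate best with the deep one. Among 23 deep kept CV cells 2 of 5 did, and the deep barcode ranked 1, 2, 2, 1 and 6, at low correlations of 0.199 to 0.238. This leaves the explanation open, and the 5 kept barcodes count as separate cells in the CV shares. Stray reads of the deep barcode alone are argued against, since 28.3% to 38.6% of the genes at 1000 CPM or more in a shallow barcode lay under 10 CPM in the deep one, against 31.9% to 46.7% in 6 other shallow kept CV barcodes. No biological explanation was tested.

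Cells with both a Tas2r and Tas1r3 may be doublets, cells that took up free RNA, or cells that express both. In FP the 13 cells chosen by a Tas2r at 50 CPM had pooled Tas1r3 at 97.48 CPM. That is 166 times (80.4 to 413.5, counting error only) the 0.587 CPM (7 counts) of the keratinocyte-like barcodes. It argues against free RNA at the level of those barcodes as the source of the pooled Tas1r3. For single cells with Tas1r3 at 50 CPM it adds nothing, since they exceed that level by definition. Of the 1560 Tas1r3 counts in these 13 cells, 1550 came from 4 cells, and the other 9 cells had 1.15 CPM (10 counts), where free RNA stays open, as it does in CV, whose library held 0 keratinocyte-like barcodes. Doublets should detect more genes, and the median over cells with a Tas2r alone was 1.02 times in FP (4 and 9 cells) and 1.11 times in CV (7 and 21 cells), which lies between the bounds of 1.3 and 1.0 set in advance, so doublets and co-expression cannot be told apart with these few cells. Papilla type as an explanation was not tested.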

How the results depend on the processing

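The alternatives at 50 CPM, the ones without adjoining or doubtful barcodes and the comparison of receptor classes in FP were chosen after seeing the data. No paired analysis was possible because each group has 1 library. A mitochondrial share of at most 0.6% left 0 cells in FP and 0 in CV, so no other result has a value there. Kept CV cells rose from 32 to 56 with no Gnat3 limit, 50 with any Gnat3 count and 61 with every barcode. Tas1r3 shares fell from 76.2% in FP and 53.1% in CV to 52.4% and 31.2% at 3 counts, 38.1% and 21.9% at 50 CPM (38.1% and 28% with over 1000 genes as well), to 47.6% in FP when thinned and to 34.4% in CV over every barcode. The FP Tas2r share of 95.2% became 61.9% at 50 CPM, with or without the 1000-gene limit, 71.4% when thinned and 100% at up to 60% mitochondrial counts, while the CV share of 90.6% stayed within its interval under each alternative that gave a value. Tas1r3 among Tas2r cells fell from 80% in FP and 58.6% in CV to 43.8% and 35.7% at 3 counts, 30.8% and 25% at 50 CPM (30.8% and 29.2% with over 1000 genes) and 46.7% in FP when thinned. Fewer stray counts pass the stricter rules by construction, and the cause of the other shifts was not tested.

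Of the 24 named genes, 23 or 24 stayed at least 2-fold under each alternative that gave a value, and 23 were chosen again with no low-value filter. Of 22 lists, 14 kept their side of 0 with no Gnat3 limit, with any Gnat3 count or with every barcode, and so did 13 of the 18 with a value without the 10% highest totals, while bitter receptor and tuft gene medians kept theirs throughout. Etv1 turned to -1.24, -1.26 and -1.22 (log2) with no Gnat3 limit, any Gnat3 count and every barcode, through 1 CV barcode with 903 CPM, and Cd36 to -0.14 without the 10% highest totals. The all-gene median moved from -0.05 to 0.15 with mean CPM per cell and to 0.08 with TMM. CV cells with Tas1r3 and no Tas2r numbered 0, or 1 with no Gnat3 limit, any Gnat3 count or every barcode, so the planned scaling, weighting and filter alternatives of that comparison were not run. Of its 16 genes in FP, 15 or 16 stayed 2-fold under each alternative run. Those genes were also chosen as the largest ratios of the same cells, so that count was largely fixed in advance. Clusters numbered 3 to 6 and barcodes changed cluster, with adjusted Rand indices of 0.580 to 0.683 against the main clustering. Depth limits detection in the 7 kept CV cells with under 1000 genes, of which FP had none.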

Other observations

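The test of neighbouring bitter receptors was written down before its result was seen, and the genes in the other 2 paragraphs were singled out after their values were seen.

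High Tas1r1 or Tas1r2 went with Kit and Etv1 in 3 deep barcodes, 2 of FP and 1 of CV, but not in all cells. The 2 FP cells with Tas1r1 at 5800 and 5415 CPM had Kit at 865 and 822 CPM and Etv1 at 177 and 646 CPM. The CV barcode with Tas1r2 at 2211 CPM, which was not kept, had Kit at 683 CPM, Etv1 at 903 CPM and Tmem45b at 587 CPM, while the highest Kit level among kept CV cells was 2.40 CPM. That barcode also stood apart from the pooled kept CV cells by Trcg1 (4741 against 1.93 CPM), Pcdh20 (1389 against 0.372 CPM), the bone peptide gene Bglap2 (4367 against 9.65 CPM), the transcription factor gene Foxa2 (888 against 5.01 CPM), the neuropeptide gene Calca (463 against 0.542 CPM) and Gnaq (1946 against 52.8 CPM). Of the 2 shallow barcodes with over 1000 CPM of Tas1r1 or Tas1r2, with 32726 and 49717 counts, neither had a Kit count. Kit was on in 7 kept FP cells, of which 3 had Tas1r1 at 50 CPM or more, and in none of the 8 kept CV cells with Tas1r1 on, 2 of them deep cells with Tas1r1 at 461 and 467 CPM.

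The homeobox gene Tlx1 was also present outside the taste cells of the FP library. Pooled over the 7 keratinocyte-like barcodes, Tlx1 had 160 CPM (153 to 168) and was on in 3. It was not listed for any of the 32 kept or 29 other CV barcodes, and it was taken as 0 there.

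Bitter receptors that lie close together could be switched on together, and this hypothesis was tested in CV over 23 receptors on chromosome 6 that were on in at least 3 cells. Across their 253 pairs, the Spearman correlation of genomic distance with the overlap of their cells was -0.15, a figure across pairs, which are not independent. Of 10000 shuffles of the positions, 7.97% gave a lower correlation, which lies between the bounds of 2.5% and 10% set in advance and leaves the hypothesis open. The median overlap was 22.2% for the 90 pairs within 500 kb and 17.6% for the 163 pairs further apart, and reads shared between neighbouring paralogs would raise the first.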
